A study of Homo sapiens with 12 samples.

How the data were processed

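Messenger RNA levels were measured by sequencing in 12 libraries of 2 human cell lines, 3 with control siRNA and 3 with KMT9a siRNA in each line. Groups and replicate numbers were taken from the sample titles. The submitters' processing notes name STAR, HOMER and edgeR and the hg19 build, with no versions, roles or settings. The sources used here do not give strand handling or filters. For each cell line the authors deposited a table of 38763 RefSeq transcript rows, with coordinates on hg19, 6 columns of a scaled signal per transcript, and the authors' own log2 fold change, p-value and adjusted p-value, per the file headers.

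The deposited signal values are not raw counts: within each table all columns sum to nearly the same total. Every value was a whole multiple of a step particular to its library, within a tolerance of 0.1 step for 100% of values above 0. Even multiples were in excess, so that 1 step stands for an end of a read pair and 2 steps for a pair. Whole reads were recovered on this basis, and read numbers here were computed from the deposited values. The tables list 24359 gene symbols; 1182 rows without annotation kept their RefSeq accession. A gene with several transcript rows was represented by the row with the highest mean, because reads of shared exons were present in several rows. Paralogs, pseudogenes and overlapping genes can share reads, and antisense genes cannot be told apart without strand.

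The design fixed before the data were examined assumed raw counts and the quasi-likelihood test of edgeR. Because the values are scaled, the main test was instead limma 3.58.1 with a mean-variance trend on log2 of the TMM-scaled value plus a pseudocount of 1 on the deposited scale, in R 4.3.3, fitted within each table, since the tables were scaled separately. The edgeR 4.0.16 test on the recovered reads became an added alternative and called 5595 genes higher and 5552 lower in PC-3M, and 1 higher and 5 lower in MCF10A. A fold change on this scale understates the change of low genes. Genes were kept by the edgeR filter on recovered reads, with a minimum count of 10 and a minimum total of 15, which left 14958 genes in PC-3M and 1049 in MCF10A. The libraries held 40236221 to 53401602 read ends in genes in PC-3M and 181064 to 255642 in MCF10A. CPM values are TMM-scaled and relative to the total over tested genes, and CPM in read pairs or read ends are relative to all those in genes, without TMM. Adjusted p-values are Benjamini-Hochberg over the tested genes of a line, with a threshold of 0.05. The difference between lines was tested as a z statistic from both fits, with rows matched by RefSeq identifier, the fallback fixed for tables without raw counts.

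The 39 gene lists, covering proliferation, metabolism, translation, stress, signalling, adhesion, identity and markers of other cell types, were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera on the same log2 values, in place of the planned log2 CPM values, with a preset correlation of 0.01 and again with an estimated correlation, and with fry. The names of genes in the text follow a rule fixed at the same time. It takes N6AMT1 and TRMT112, the 8 largest changes per direction past the threshold with a mean of at least 5 CPM and no overlap of the groups (uncharacterized, noncoding and pseudogene symbols left out), up to 4 members of smallest p from each list that passed or had at least 3 changed members, and 5 genes per direction of the difference between lines; where space was short fewer list members were printed. Alternatives covered the scaling, the filter, all transcript rows, the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, 1 fit over all 12 libraries and stricter thresholds; added after seeing the data were the edgeR test, pseudocounts of 0.25 and 5, averaged MCF10A control replicates 1 and 2, correction for GC content and length, and thinning to equal depth.

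The analysis was tested on simulated counts with the real means and library sizes and 200 changed genes per line. Against the calls in the data, this was a far smaller share of the genes in PC-3M and a far larger share in MCF10A. Recovery at an adjusted p rises with that share, so the recoveries of the 2 lines were obtained under unlike settings. In PC-3M, over 14934 genes, limma recovered 80.6% of 1.5-fold, 87.9% of 2-fold and 98.5% of 4-fold changes, and called 13 of 14735 unchanged genes. In MCF10A, over 1035 genes, it recovered 4.55% of 1.5-fold, 20.0% of 2-fold and 90.5% of 4-fold changes and called 5 of 841 unchanged genes. The z test of the difference, over 784 genes, recovered 9.68%, 40.0% and 96.8% of these sizes when the change was in PC-3M alone. Intervals and floors, taken at 3 read pairs, cover counting error only, since reads without molecular identifiers are not independent molecules. GC content and names came from GRCh38 annotation, whose coordinates were not used here.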

Results

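The RNA of 2 human cell lines was sequenced after transfection with siRNA against KMT9a or with control siRNA. KMT9a is the product of N6AMT1, a methyltransferase that acts as a heterodimer with TRMT112. PC-3M is a metastatic derivative of the PC-3 prostate cancer line, and MCF10A is a non-transformed line of breast epithelial cells. Each of the 4 groups held 3 libraries labelled as biological replicates, 12 libraries in total. The labels do not say whether replicates came from separate cultures on separate days, so p-values measure the spread between these samples. The PC-3M libraries held 40236221 to 53401602 read ends in genes, 2 to a pair, and 17067 to 17540 genes were above 0. The MCF10A libraries held 181064 to 255642 read ends in genes, and 2298 to 2594 genes were above 0. The 10 most abundant genes took 4.36% to 5.76% of the reads in PC-3M libraries and 24.2% to 32.4% in MCF10A libraries. The series title names the questions: control of metabolism and of proliferation in castration-resistant prostate cancer cells.

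The targeted gene was measured first. In PC-3M, N6AMT1 (hg19 chromosome 21, 30244513 to 30257693, minus strand) stood at 11.5 ± 0.528 CPM (SD, n = 3) with control siRNA and at 2.81 ± 0.213 CPM (SD, n = 3) with KMT9a siRNA. It was 4.05-fold lower, a log2 fold change of -2.02 (SE 0.107, limma, adjusted p = 3.47e-09), and all 3 knockdown libraries lay below all 3 control libraries. The authors' deposited table gives N6AMT1 a log2 fold change of -2.06. TRMT112 (chromosome 11, 64084165 to 64085033, minus strand) fell from 154 ± 4.48 to 108 ± 5.68 CPM (SD, n = 3), a log2 fold change of -0.51 (SE 0.0541, limma, adjusted p = 2.36e-06). In MCF10A, N6AMT1 was listed at 0 in all 6 libraries, with control siRNA as with KMT9a siRNA. A level equal to that of the PC-3M controls would have given 1.10 to 1.56 read pairs per MCF10A library, and a count of 0 in a single library allows up to 23.5 to 33.1 CPM in read pairs, counting error only. Counts of 0 in all 3 control libraries together set a tighter bound, which was not computed. The knockdown labels were therefore checked in PC-3M and could not be checked in MCF10A at this depth.

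**Figure D1:**
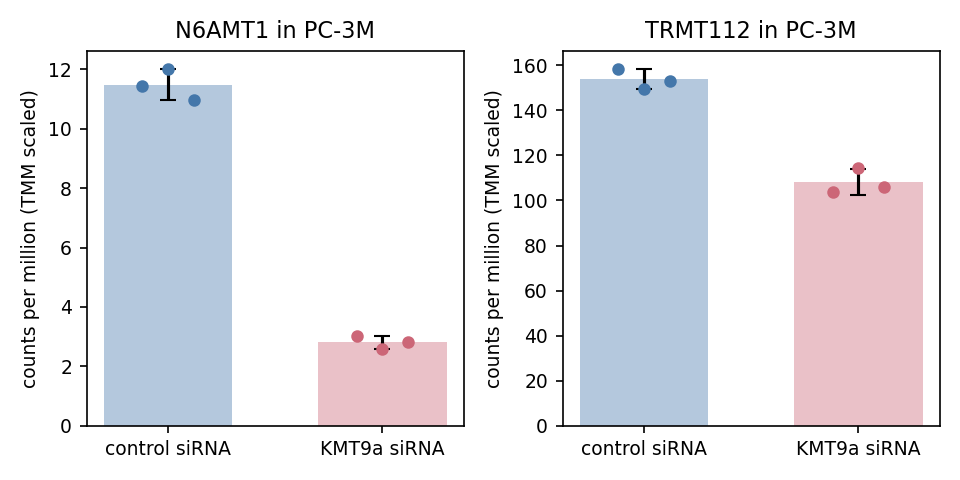
N6AMT1 and TRMT112 in the PC-3M libraries, in TMM-scaled CPM; points are the 3 libraries of each group, bars their mean and error bars the SD. N6AMT1 stood at 11.5 CPM with control siRNA and 2.81 CPM with KMT9a siRNA, and TRMT112 at 154 and 108 CPM.

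With KMT9a siRNA, the largest gains in PC-3M among genes with a mean of at least 5 CPM were in INHBA, which encodes the inhibin beta A subunit and rose from 2.49 ± 0.252 to 320 ± 16.4 CPM (log2 fold change 6.98), and HMOX1, heme oxygenase 1, which rose from 21.1 ± 1.12 to 2653 ± 189 CPM (6.97; SD, n = 3). The next largest log2 gains were in the decoy receptor gene IL13RA2 (5.99), the chemokine gene CCL20 (5.45), the calcium-binding protein gene CALB1 (5.40), the serpin gene SERPINB2 (5.22), the integrin subunit gene ITGB4 (5.01) and the FGF-binding protein gene FGFBP1 (4.78). The deepest log2 losses at that level were in HSD17B13 (-4.92), a lipid droplet protein gene, the complement gene C5 (-4.72), the matrix protein gene SPARC (-4.58) and the vesicle GTPase gene RAB3A (-4.31). BIRC5, which encodes survivin, fell from 81.1 ± 2.86 to 4.22 ± 0.0989 CPM (-4.25; SD, n = 3), followed by the transcription factor gene MYB (-4.11), the transporter gene ABCA8 (-4.07) and the inflammasome gene NLRP3 (-4.03). Every one of these 16 genes separated the 3 knockdown from the 3 control libraries, with adjusted p of 2.82e-09 or lower for ABCA8 and the other 15 by limma. INHBA lies on hg19 chromosome 7 at 41728601 to 41742706, HMOX1 on chromosome 22 at 35777060 to 35790207, HSD17B13 on chromosome 4 at 88224941 to 88244056 and C5 on chromosome 9 at 123714614 to 123812554.

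Over all genes, 11139 of 14958 tested genes changed in PC-3M at an adjusted p under 0.05 (limma with a mean-variance trend), 5564 higher and 5575 lower. A change of at least 2-fold was found in 1847 of the higher and 1772 of the lower genes. The knockdown and control libraries did not overlap for 77.0% of genes, where chance gives 10%. Scaling by library totals alone shifted the median log2 fold change of all genes to -0.17, against 0.00099 with TMM, and gave 4384 higher and 6821 lower genes, so that directions here are relative to the TMM-scaled middle of the genes. KMT9a siRNA replicate 2 differed more from the other knockdown libraries (chi-square over degrees of freedom 11.1 and 13.4) than these from each other (2.37), and without it 11815 genes passed. In the authors' deposited table, 10993 of the genes tested here were past 0.05, and 10866 of them were past it here with the same sign.

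Of the 6 lists on proliferation, 4 were lower in PC-3M. Of 38 G2/M and mitosis genes, 36 were lower and 1 was higher, with a median log2 fold change of -2.44 (camera adjusted p = 1.84e-14; adjusted p = 0.336 with an estimated correlation). Among them PRC1 fell by 2.94, the proliferation marker MKI67 by 3.19 and CCNB1, which encodes cyclin B1, by 2.35 on the log2 scale. Of 36 genes of replication origins and forks, 31 were lower and 1 was higher (median -1.06, camera adjusted p = 1.04e-07; adjusted p = 0.179 with an estimated correlation); the helicase gene MCM6 fell by 2.30, the flap endonuclease gene FEN1 by 1.64 and the topoisomerase gene TOP2A by 2.53. The G1/S and E2F list had 17 of 24 genes lower and 4 higher (median -1.19, camera adjusted p = 0.00437; adjusted p = 0.449 with an estimated correlation). Within it the transcription factor gene E2F1 fell from 18.3 ± 1.23 to 1.67 ± 0.213 CPM while E2F7, an E2F repressor gene, rose from 37.0 ± 1.55 to 129 ± 5.73 CPM (SD, n = 3). Of 22 DNA repair genes, 16 were lower and 2 higher (median -1.13, camera adjusted p = 0.00172; adjusted p = 0.345 with an estimated correlation), including POLQ (-3.37), BRCA1 (-2.44) and RAD51AP1 (-2.46). When genes under a mean of 5 CPM were left out, the DNA repair list (median -0.49, camera adjusted p = 0.132) and the G1/S list (median -0.55, camera adjusted p = 0.0749) no longer passed. That mean was taken over all 6 libraries, so a gene could be left out because it fell. BRCA1, at 6.96 CPM in the controls, had a mean of 4.12 CPM over all libraries. The smaller medians therefore do not show how far these 2 lists rest on low genes. The other 2 lists did not pass: replication-dependent histone genes, with 6 of 18 higher and 7 lower (camera adjusted p = 0.956), and p53-regulated genes and CDK inhibitors, with 11 of 27 higher and 11 lower (0.772). In the p53 list the CDK inhibitor gene CDKN2B rose from 125 ± 5.14 to 816 ± 23.6 CPM (SD, n = 3), CDKN1A by 1.90 and CDKN2A by 1.62 log2 units.

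Metabolic genes followed several directions. All 37 oxidative phosphorylation genes were lower (median -0.73, camera adjusted p = 3.81e-11; adjusted p = 0.0995 with an estimated correlation). The ATP synthase gene ATP5B fell from 2245 ± 29.1 to 861 ± 32.5 CPM and ATP5G1 from 232 ± 6.09 to 64.8 ± 5.0 CPM (SD, n = 3). Of 29 tricarboxylic acid cycle genes, 17 were lower and 5 higher (median -0.35, camera adjusted p = 0.0144; adjusted p = 0.369 with an estimated correlation), including the succinate dehydrogenase gene SDHC (-2.03) and the dihydrolipoamide dehydrogenase gene DLD (-1.29). Glycolysis genes were lower in 16 and higher in 5 of 22 cases (median -0.36, camera adjusted p = 0.0154; adjusted p = 0.507 with an estimated correlation); of the lactate transporter genes, SLC16A1 fell by 1.58 and SLC16A3 rose by 1.53. Purine and pyrimidine synthesis genes were lower in 16 and higher in 2 of 20 cases (median -0.73, camera adjusted p = 0.000375; adjusted p = 0.336 with an estimated correlation), led by the ribonucleotide reductase gene RRM2, which fell from 95.1 ± 4.05 to 6.67 ± 1.41 CPM (SD, n = 3), and with IMPDH2 at -1.22. The serine, glycine and folate list had 14 of 20 genes lower and 3 higher (median -0.64, camera adjusted p = 0.00546; adjusted p = 0.345 with an estimated correlation). Its serine synthesis genes PHGDH (-2.47) and PSAT1 (-2.15) and the thymidylate synthase gene TYMS (-1.98) fell. Cholesterol biosynthesis genes went the other way, with 20 of 25 higher and 4 lower (median 0.58, camera adjusted p = 0.00171; adjusted p = 0.277 with an estimated correlation); MSMO1 rose by 1.41, while PMVK fell by 1.70. Fatty acid genes were split, 12 higher and 9 lower of 22 (camera adjusted p = 0.738), as were pentose phosphate genes, 4 higher and 5 lower of 10 (camera adjusted p = 0.956). Among these the desaturase gene SCD rose by 1.24 and the dehydrogenase gene PGD by 2.79, and the elongase gene ELOVL5 fell by 2.41.

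Ribosomal protein genes and ribosome biogenesis genes moved in opposite directions. Of 33 cytosolic ribosomal protein genes, 25 were higher and 1 lower, by a small amount (median 0.31, camera adjusted p = 0.000581; adjusted p = 0.467 with an estimated correlation); RPS9 rose by 0.89 and RPS6 by 0.70. Of 32 MYC target and ribosome biogenesis genes, 23 were lower and 6 higher (median -0.35, camera adjusted p = 0.00437; adjusted p = 0.369 with an estimated correlation), including RRP12 (-1.28), NHP2 (-0.94) and BOP1 (-0.79). Genes that the transcription factor ATF4 regulates under amino acid stress were lower in 18 and higher in 4 of 27 cases (median -0.44, camera adjusted p = 0.00172; adjusted p = 0.483 with an estimated correlation). The asparagine synthetase gene ASNS fell from 100 ± 7.62 to 19.8 ± 1.12 CPM (SD, n = 3), and CHAC1 fell by 2.41. Chaperone genes of the unfolded protein response were lower in 12 and higher in 3 of 18 cases (median -0.45, camera adjusted p = 0.0128; adjusted p = 0.476 with an estimated correlation), with EDEM1 at -1.12 and CANX at -0.99. Heat shock protein genes were lower in 9 and higher in 1 of 14 cases without passing as a list (camera adjusted p = 0.112), and the higher gene was DNAJB1 (1.66). NRF2-regulated antioxidant genes were split, 8 higher and 10 lower of 20 (camera adjusted p = 0.861): HMOX1 and the ferritin gene FTH1 (1.12) rose while OSGIN1 fell by 2.08.

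Of 23 integrin, laminin and focal adhesion genes, 19 were higher and 2 lower (median 0.99, camera adjusted p = 8.65e-06; adjusted p = 0.179 with an estimated correlation). ITGA3 rose from 70.3 ± 1.26 to 1745 ± 201 CPM and ITGB4 from 22.8 ± 2.36 to 739 ± 96.8 CPM (SD, n = 3). Of 12 basal epithelial marker genes, 10 were higher and 0 lower (median 1.49, camera adjusted p = 0.00138; adjusted p = 0.179 with an estimated correlation), including EGFR (2.28) and the desmosomal cadherin gene DSC3 (2.05). YAP and TAZ target genes were higher in 10 and lower in 3 of 16 cases (median 0.72, camera adjusted p = 0.0300; adjusted p = 0.473 with an estimated correlation), with CYR61 at 2.41 and AMOTL2 at 2.15. The ERK-regulated immediate early and feedback list had 13 of 20 genes higher and 5 lower (median 0.60, camera adjusted p = 0.0217; adjusted p = 0.483 with an estimated correlation); the phosphatase gene DUSP5 rose by 2.72 and the ERK inhibitor gene SPRY4 fell by 1.47. NF-kB and inflammatory genes were higher in 16 and lower in 2 of 19 cases (median 1.01, camera adjusted p = 0.000978; adjusted p = 0.369 with an estimated correlation), with BIRC3 at 2.35 and the adhesion molecule gene ICAM1 falling by 1.99. MHC class I and antigen presentation genes were higher in 11 and lower in 2 of 13 cases (median 0.77, camera adjusted p = 0.0144; adjusted p = 0.467 with an estimated correlation), including HLA-E (1.21) and TAPBP (1.08). Interferon-stimulated genes were higher in 15 and lower in 5 of 23 cases (median 0.94, camera adjusted p = 0.0483; adjusted p = 0.336 with an estimated correlation); IRF7 rose by 2.84 and IFIT1 fell by 2.28. The interferon list no longer passed without KMT9a siRNA replicate 2 (median 1.17, camera adjusted p = 0.0843) or without KMT9a siRNA replicate 3 (median 0.94, camera adjusted p = 0.0534). Nor did it pass without genes under a mean of 5 CPM (median 0.60, camera adjusted p = 0.270).

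**Figure D2:**
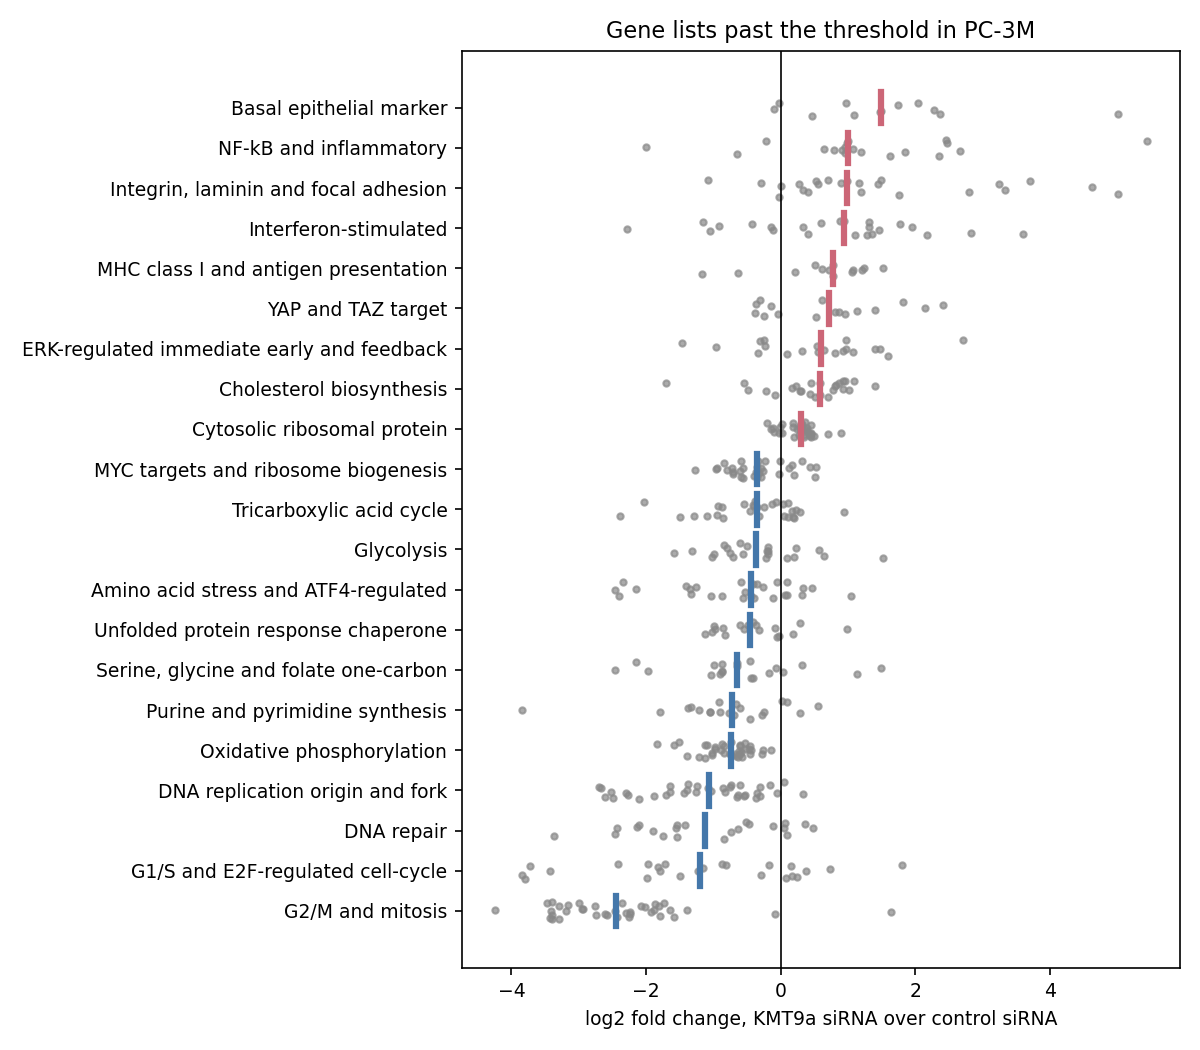
Log2 fold change (horizontal axis, KMT9a siRNA over control siRNA, PC-3M) of each tested member of the 21 gene lists past the threshold (vertical axis); points are genes and bars are list medians, blue where lower and red where higher. Medians run from -2.44 for G2/M and mitosis genes to 1.49 for basal epithelial marker genes.

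In total 21 of 38 tested lists passed in PC-3M with camera at a preset correlation of 0.01, 9 higher and 12 lower. With an estimated correlation 0 passed by camera and 5 had an unadjusted p under 0.05, and the rotation test fry, which asks whether a list moves on balance one way without comparing it with other genes, passed 35. Adjusted over the list alone, the numbers of changed members differed from those over all genes for 4 lists: replication origins and forks (32 lower), the tricarboxylic acid cycle (6 higher, 18 lower), lysosome and autophagy (10 higher, 9 lower) and apoptosis regulators (11 higher, 11 lower).

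A fit over all 12 libraries, which shares the larger spread of MCF10A, left RPS6 (limma adjusted p = 0.133) and CANX (0.12) short of the threshold.

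The remaining lists did not pass in PC-3M. Epithelial adhesion and keratin genes were higher in 13 and lower in 4 of 19 cases (camera adjusted p = 0.0574), with KRT19 rising by 1.88 and CDH1, which encodes E-cadherin, by 1.29. Mesenchymal and extracellular matrix genes were split, 14 higher and 8 lower of 24 (camera adjusted p = 0.181): ITGA5 rose by 3.15 and TNC by 2.23, and COL1A2 fell by 2.71. Androgen receptor and target genes had 6 of 10 lower and 2 higher (camera adjusted p = 0.177), with the prostatic acid phosphatase gene ACPP at -3.65 and HOXB13 at -1.10. Histone lysine methyltransferase genes were higher in 15 and lower in 8 of 27 cases (camera adjusted p = 0.182), including KMT2A (1.16) and SETD2 (1.10). Hypoxia-inducible genes had 9 of 21 higher and 11 lower (camera adjusted p = 0.564), lysosome and autophagy genes 9 higher and 9 lower of 24 (0.772), and apoptosis regulators 11 higher and 10 lower of 25 (0.941). Translation termination genes and genes of other TRMT112 partners had 7 higher and 7 lower of 17 (camera adjusted p = 0.956), with GSPT1 at -0.82 and METTL5 at -0.77. Markers of other cell types did not pass either: fibroblast and smooth muscle genes had 1 higher and 2 lower of 7 (camera adjusted p = 0.477), leukocyte and endothelial genes 4 higher and 2 lower of 7 (0.560) and breast luminal genes 5 higher and 5 lower of 11 (0.852). The neuroendocrine list had 4 measured members, 1 higher and 1 lower, too few to test. Median, mean and test differed in sign for 4 lists, none past the threshold: breast luminal, NRF2, pentose phosphate and replication-dependent histone genes.

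In MCF10A, 5 genes passed the test. The knockdown labels could not be checked in this line. Its fold changes may not describe MCF10A cells, for reasons given under the flagged results. EFNB2, which encodes the ligand ephrin-B2, rose from 281 ± 46.0 to 966 ± 175 CPM (log2 fold change 1.74). The bicarbonate transporter gene SLC4A7 fell from 454 ± 19.9 to 60.9 ± 35.2 CPM (-2.86), and SPARC from 1045 ± 174 to 279 ± 55.8 CPM (-1.88; SD, n = 3). The ubiquitin ligase gene TRIM8 fell by 1.54 and the receptor phosphatase gene PTPRF by 1.52 log2 units. The adjusted p was 0.0390 for EFNB2, SLC4A7, SPARC and PTPRF and 0.0446 for TRIM8 (limma). With library totals only SPARC alone passed (adjusted p = 0.0805 for the other 4), and with every deposited row tested none did (adjusted p = 0.0500351 for each, 360 at an unadjusted p under 0.05). On hg19, EFNB2 lies on chromosome 13 at 107142079 to 107187388, SLC4A7 on chromosome 3 at 27414214 to 27498245, TRIM8 on chromosome 10 at 104404252 to 104418076, PTPRF on chromosome 1 at 43996547 to 44089343 and SPARC on chromosome 5 at 151041009 to 151066517.

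Only 1049 genes entered the MCF10A test, of which 152 had an unadjusted p under 0.05, and the 3 knockdown and 3 control libraries did not overlap for 28.2% of genes, where chance gives 10%. In the authors' deposited table, 18 of these genes were past 0.05, the 5 named here among them. Mesenchymal and extracellular matrix genes were lower as a list of 5 tested members (median -1.44, camera adjusted p = 0.0160; adjusted p = 0.140 with an estimated correlation), of which 1, SPARC, was past the threshold over all genes and 3 were adjusted over the list alone. The list no longer passed without KMT9a siRNA replicate 3 (median -1.26, camera adjusted p = 0.0648) or with every deposited row (median -0.45, camera adjusted p = 0.104). Its other named members were MMP14 at -1.44 (limma adjusted p = 0.143), TNC at -1.48 (0.229) and FN1 at 0.43 (0.568). Without KMT9a siRNA replicate 2 all 3 passed, MMP14 at -1.53 (limma adjusted p = 0.00072), TNC at -1.22 (0.026) and FN1, against the list's direction, at 0.87 (0.00247). The fatty acid list (5 tested genes, camera adjusted p = 0.743) and the histone lysine methyltransferase list (9 tested genes, 0.743) did not pass, and their medians and means differed in sign; the other 36 lists had too few measured genes. The cytosolic ribosomal protein list took 0.107% to 0.327% of the reads of an MCF10A library and 3.43% to 3.82% in PC-3M, and 93 of the 100 most abundant genes of the PC-3M controls stood at no more than 100 CPM in read pairs in MCF10A, where PABPC1, EIF4G2 and HNRNPA2B1 were the most abundant.

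KMT9a siRNA replicate 2 stood apart within MCF10A, with correlations of 0.821 and 0.874 across genes to the other knockdown libraries against 0.960 between those; without it 170 genes passed, 76 higher and 94 lower, the 5 genes above among them. Control replicates 1 and 2 differed by less than the sampling noise of read pairs (chi-square over degrees of freedom 0.791), against 1.30 between replicates 1 and 3 and 1.06 between 2 and 3. This statistic takes 2 read ends as 1 pair and would be larger if counted in read ends. In control replicate 1, 691 transcript rows held a single read end. Counted as 1 sample, control replicates 1 and 2 left 0 genes past the threshold by limma, with 72 at an unadjusted p under 0.05. Leaving out control replicate 1, 2 or 3 or KMT9a siRNA replicate 1 also gave 0 genes by limma, with 75, 87, 93 and 121 at an unadjusted p under 0.05, and leaving out KMT9a siRNA replicate 3 gave 8.

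Both lines were treated with siRNA against the same gene, and 797 genes could be tested for a different response. MCF10A fold changes may not describe MCF10A cells, for reasons given under the flagged results. A difference here may therefore not be one between the responses of the 2 cell lines. PTBP2, named below, is among the conserved RNA-binding protein genes weighed there. The difference of the log2 fold changes, PC-3M minus MCF10A, passed for 220 genes, 155 of them above 0 and 65 below. The pseudocount of 1 weighs more in MCF10A, where the values of control replicate 1 sum to 231587, against 45253526 in PC-3M. Fold changes are therefore understated more in MCF10A. With pseudocounts of 0.25 and 5, the difference passed for 202 and 278 genes. The transcription factor gene FOXQ1 had a log2 fold change of 3.46 in PC-3M and -0.72 in MCF10A, the activin-binding protein gene FST 2.20 and -1.97, SLC4A7 1.18 and -2.86, the choline transporter gene SLC44A1 3.02 and -0.83, and the matrix gene TNC 2.23 and -1.48. In the other direction SPARC had -4.58 and -1.88, the splicing regulator gene PTBP2 -2.20 and 0.50, the cytokinesis kinase gene CIT -2.73 and -0.03, the enzyme gene GMDS -1.69 and 0.96, and the chromatin remodeler gene HELLS -1.77 and 0.44. FOXQ1 was low in PC-3M, with a mean of 0.647 CPM over the 6 libraries. Of the genes named in this comparison, SLC4A7 and SPARC were past the threshold in both lines, SLC4A7 in opposite directions and SPARC lower in both. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.038 and a Spearman rho of 0.021, and 50.3% had the same sign. Of the genes past the threshold, 1 was higher in both lines, against 0.575 by chance, with too few calls for a test, and 2 were lower in both, against 0.979 (Fisher's exact test, two-sided, p = 0.252). The median SE of a log2 fold change over these genes was 0.060 in PC-3M and 0.387 in MCF10A, so that the MCF10A libraries set the precision of each difference. Without MCF10A control replicate 1, 2 or 3 the number of genes past the threshold was 125, 129 or 132, without MCF10A KMT9a siRNA replicate 2 or 3 it was 342 or 359, and without replicate 2 r was 0.122.

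**Figure D3:**
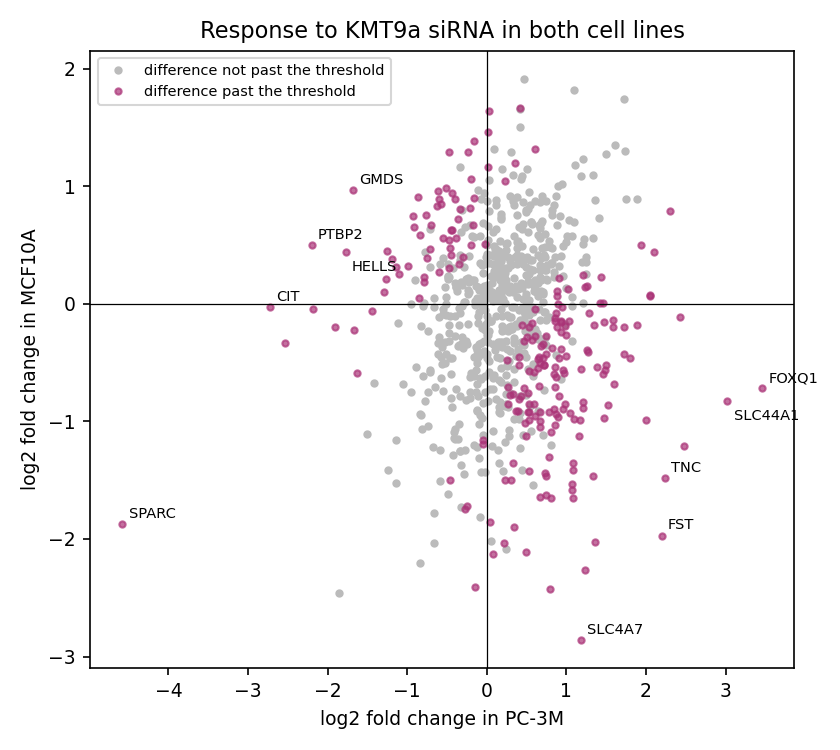
Log2 fold change with KMT9a siRNA in PC-3M (horizontal axis) against MCF10A (vertical axis) for the 797 genes tested in both lines; each point is a gene, purple where the difference between lines passed the threshold (220 genes), and the 10 named genes are labelled. The points show no common trend, with r = 0.038 across genes. MCF10A fold changes may not describe MCF10A cells, as set out under the flagged results.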

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

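The splits of the libraries, the test of depth in MCF10A and the tests of its KMT9a siRNA replicate 2 were set out before their results were seen; the tests of scaling, GC content, length and depth in PC-3M, of the MCF10A ribosomal protein share and of conserved genes were chosen only after the result was seen.

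Of the 220 genes whose response differed between the lines by the test of the difference itself, the fixed rule names 10. The log2 response in PC-3M minus that in MCF10A was 4.18 for FOXQ1, 4.17 for FST, 4.04 for SLC4A7, 3.85 for SLC44A1 and 3.72 for TNC, and -2.70 for SPARC, -2.70 for PTBP2, -2.70 for CIT, -2.65 for GMDS and -2.22 for HELLS, with adjusted p from 1.23e-29 for SLC44A1 to 0.00128 for CIT. In 100 drawn splits of the libraries of both lines, the real one was the only 1 to give as many as 220 genes. Splits that regrouped PC-3M gave at most 32 genes. These draws reuse the few regroupings of PC-3M, whose 6 libraries allow only 10 splits, the real one included. That is too few for a share under 0.05, so the draws do not decide on the grouping of PC-3M. Only 12 draws, the real one included, kept the PC-3M libraries as labelled. With the MCF10A libraries regrouped, the others of these gave 72 to 215 genes. They are too few and too close to 220 to decide on the grouping of MCF10A.

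The MCF10A libraries held few genes and little of the usual housekeeping transcripts. Low depth is argued against: PC-3M control libraries thinned to the MCF10A read totals still showed at least 11214 genes above 0, against at most 2594. The ribosomal protein list took at most 0.327% of an MCF10A library's reads, against at least 3.43% in PC-3M. GAPDH stood at 0 to 75.7 CPM in read pairs in MCF10A, against 4282 to 6515 in PC-3M. ACTB stood at 0 to 52.1, against 602 to 1199. For these genes, the values argue against the cell line's own expression programme, though no other MCF10A profile was available to set a bound. A candidate explanation is that many reads came from another organism and aligned to the human genome only where sequences are nearly identical: 26 RNA-binding protein genes, picked as having such segments, had a median of 1776 CPM in read ends in MCF10A, at percentile 100 of 10000 lists matched on PC-3M expression, whose highest median was 15, and the 22 of them outside the 10 most abundant genes were also at percentile 100. The list was written after the most abundant genes had been seen, and the organism was not tested, so this remains a hypothesis, and MCF10A fold changes may not describe MCF10A cells.

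Of the tested PC-3M genes 74.5% changed. The spread between replicates was small, with a correlation of 0.996 across genes for each pair of control libraries and a median SE of 0.085. Small changes could therefore pass, and 6745 genes passed with a change of at least 1.5-fold. The labels do not say whether replicates were separate cultures, so the share may depend on how they were made. Another scaling left at least 11146 genes past the threshold against 11139, but library totals only kept 9959 of these calls and changed the sign of 110 genes. Every scaling used is relative to the other genes, so these counts cannot test a change in total RNA. Removing trends with GC content and transcript length left 11456 of 14447 against 10823 of the same genes, and thinning all libraries to 40236221 read ends left 10967. The counts argue against the choice among these scalings, GC content with length, and unequal depth of the libraries, each as the whole cause. Thinning to the shallowest library kept a high depth, so how far depth itself let small changes pass was not tested. The 6 libraries allow 10 splits, too few for a share under 0.05; 1 of 10, the real one, gave as many as 11139 genes (highest other 0), and 1 of 10 as many as 21 gene lists (highest other 17). Loss of KMT9a remains open as a biological explanation, and so does an off-target effect of the siRNA, which may give a broad response and cannot be separated here because the labels name no further siRNA or rescue.

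KMT9a siRNA replicate 2 of MCF10A stood apart from the other libraries. With all MCF10A libraries thinned to its depth, its chi-square over degrees of freedom against another knockdown library was still at least 14.3, against 2.25 between replicates 1 and 3, which argues against depth. Its deviation went with shorter transcripts (Spearman rho -0.286 across genes), but removing trends with length and GC content raised its lower correlation only from 0.822 to 0.841, below the 0.960 of replicates 1 and 3. The cause stays open, and no biological explanation was tested. The 10 splits of the MCF10A libraries are too few for a share under 0.05; 1 of 10, the real one, gave as many as 5 genes (highest other 0), and 2 of 10 gave as many as 1 list (highest other 1).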

How the results depend on the processing

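Added after seeing the data were the edgeR test, the pseudocounts, the averaged control replicates, the GC and length correction and the thinning; the other settings were planned. N6AMT1 in PC-3M stayed lower and past the threshold under every alternative run, and N6AMT1 in MCF10A, listed at 0, gave no value. No named gene, gene list or difference between lines reversed under any alternative in which it was tested. Among all 11139 genes changed in PC-3M, 110 changed sign, past the threshold or not, with library totals only and 136 after the GC and length correction. At the depth and spread of each line, simulated 2-fold changes were recovered in 20.0% of cases in MCF10A and in 87.9% in PC-3M. The simulated share of changed genes was larger in MCF10A, and the part of depth alone was not tested.

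The number of changed genes in PC-3M, 11139, stayed within 1.5 times under every alternative except the test of every deposited row (19819, of 26205 rows tested) and a minimum of 1.5-fold (6745), both by construction; leaving out a library gave 10428 to 11815. The split moved with library totals alone, to 39.1% higher against 50.0%. In MCF10A, 5 genes became 1 with library totals only, 66 without a filter on low counts, 0 with every deposited row, 0 with the replicate block, 51 with DESeq2, 8 with limma-voom, 161 in a fit of all 12 libraries, 0 with averaged control replicates 1 and 2, 0 at an adjusted p under 0.01, and 0 to 170 when a library was left out; the cause was not tested. Beside these counts of 0, limma gave 360, 153 and 72 at an unadjusted p under 0.05 for every deposited row, the block and the averaged controls, and 152 for the stricter threshold.

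For gene lists in PC-3M, 21 became 0 with an estimated correlation (camera, 5 at an unadjusted p under 0.05) and 35 with fry, which ask different questions; leaving out a library gave 20 to 22. In MCF10A, the 1 list, mesenchymal and extracellular matrix genes, lost its call with every deposited row (camera adjusted p = 0.104), where 3 other lists passed; the count was 0 with an estimated correlation (1 at an unadjusted p under 0.05), and 0 to 1 without a library, 0 being without KMT9a siRNA replicate 3. The 220 genes with a difference between lines became 345 with DESeq2, 991 without a filter and 564 with every deposited row. Leaving out a library gave 125 to 359. None of the 10 named differences reversed or lost its call where it was tested. FOXQ1, with a mean of 0.647 CPM in PC-3M, was not tested in the setting with a mean of at least 5 CPM. The correlation of 0.038 became -0.022 without a filter, 0.0097 with a mean of at least 5 CPM, 0.094 with every deposited row, and 0.0082 to 0.122 without a library.

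Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.041 to 0.037 in PC-3M and -0.071 to 0.157 in MCF10A, and 2 of 6 and 3 of 6 libraries correlated best with their own number. With the replicate block, 10949 genes and 22 lists passed in PC-3M, 0 genes and 1 list in MCF10A and 244 differences between lines, and the correlation was 0.038.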

Other observations

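Families of genes that share a symbol prefix were tested in PC-3M, and their members named here were chosen, after the data had been seen, 25 families of at least 10 tested genes, of which 14 passed camera with a preset correlation and 0 with an estimated correlation. Mitochondrial ribosomal protein genes fell in 69 and rose in 3 of 77 cases (median log2 fold change -0.58, camera adjusted p = 4.66e-11; adjusted p = 0.226 with an estimated correlation), with MRPL37 going from 135 ± 6.31 to 43.8 ± 0.708 CPM and MRPL19 from 73.9 ± 1.64 to 20.1 ± 2.23 CPM (SD, n = 3). The 81 genes with the prefixes RPL and RPS, paralogs such as RPL22L1 included, rose in 61 and fell in 5 cases (median 0.31, camera adjusted p = 1.22e-05; adjusted p = 0.263 with an estimated correlation). Aminoacyl-tRNA synthetase genes, which charge transfer RNAs, fell in 16 and rose in 1 of 17 cases (median -0.44, camera adjusted p = 0.00039; adjusted p = 0.263 with an estimated correlation), with YARS at -1.05 and CARS at -0.94. Genes with the prefix KIF, kinesins and the associated proteins KIFAP3 and KIF1BP, fell in 24 and rose in 7 of 35 cases (median -0.84, camera adjusted p = 0.0044; adjusted p = 0.381 with an estimated correlation): the mitotic kinesin genes KIF20A (-3.40), KIF18B (-2.99) and KIFC1 (-2.75) fell, while KIF13A rose by 2.29.

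Protocadherin genes rose in 42 and fell in 1 of 46 cases (median 1.51, camera adjusted p = 3.40e-05; adjusted p = 0.586 with an estimated correlation), but clustered protocadherin transcripts share exons, so that their rows are not independent. PCDHB2 went from 0.922 ± 0.0154 to 3.97 ± 0.525 CPM (SD, n = 3), and PCDH15 fell by 2.45. S100A genes were higher in 7 and lower in 1 of 10 cases (median 0.81, camera adjusted p = 0.0166; adjusted p = 0.263 with an estimated correlation), with S100A16 at 1.81 and S100A6 at 1.12. Genes with the prefix HSP, a set that overlaps the fixed heat shock list but leaves out DNAJB1 and takes in HSPG2, which encodes the proteoglycan perlecan, were lower in 15 and higher in 1 of 21 cases (median -0.37, camera adjusted p = 0.00487; adjusted p = 0.263 with an estimated correlation). Genes with the prefixes ITGA and ITGB, among them ITGB3BP, ITGB1BP1, ITGB1BP2 and ITGBL1, which encode no integrin subunits, were higher in 10 and lower in 3 of 20 cases (median 0.31, camera adjusted p = 0.0251; adjusted p = 0.310 with an estimated correlation). Collagen genes were split, 13 higher and 9 lower of 27 (camera adjusted p = 0.328), as were genes with the prefix SLC, 84 higher and 96 lower of 251 (0.584).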
